A study of Rattus norvegicus with 56 samples.

How the data were processed

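Total RNA was taken from the mammary gland of each rat, and 5 µg of it was made into labelled, fragmented cRNA, per the labels. For pools, equal amounts of fragmented targets of the member rats were combined to 10 µg, per the labels, so that pooling took place after labelling. The deposited values are 1 number per probe set and array for 15923 probe sets of a rat expression array. The log2 unit of the deposited values was inferred: they ran from 4.12 to 14.1, above the natural log of a 16-bit scanner's maximum, 11.1, and below its log2, 16.0. The software, the background correction and the normalization between arrays are not given in the sources used here, and the values were used as deposited. No raw intensities were used here.

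The 57 control probe sets of the array were left out, which left 15866, and no filter on dim probe sets was applied. Gene symbols came from the platform's annotation and were updated through the Entrez gene ID to the RefSeq genes of the rat assembly GRCr8, a match found for 12748 probe sets. There were 12783 probe sets with 1 symbol, 312 with several and 2771 not listed, which are unnamed here. They covered 10411 genes. Where a gene needed 1 probe set, that with the highest mean over the 24 individual arrays was used.

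Treatment was tested with limma's lmFit and eBayes on 1 array per rat, and separately in pools of 2 and of 3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Stage was tested with treatment as a covariate and the interaction in the same model. The 4 arrays of a pool of 12 share 1 mixture of labelled targets, so the difference between both pools has no test. The 27 gene lists were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation. The spread was compared as a geometric mean ratio of variances corrected for degrees of freedom. Named genes were the 12 largest rises and 12 largest falls among called probe sets with 1 symbol, up to 4 members with the smallest p of each list described, Rxra, Rxrb and Rxrg, the 6 smallest p for stage, and the 4 smallest p for the interaction and the pools against their members. These rules, the tests and most of the other settings tried were fixed before the data were examined.

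A technical axis was taken as the main component of the differences between repeat arrays, those of the same rat or of the same pool of 12, of whose variance it held 57.3%. Each array's position on it, the technical score, averaged -4.03 in treated and -2.80 in control rats (permutation test, two-sided, p = 0.649). The source label of the later arrays of the pools of 12 reads individual, while title and description give pools. As deviations from the mean of the 24 rats, across probe sets, which are not independent replicates, these arrays correlated with the first array of their pool at r = 0.565 to 0.82, each above its highest r with any rat of its group, except control pool of 12 replicate 3 (0.0801 against 0.511), whose technical score was -15.9. Permutation tests of list means used 100000 resamples, of which the smallest possible p is 1e-05. Those of treatment by stage differences used fewer. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

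Data were simulated with independent normal noise for each probe set, 100 probe sets changed by 0.5 log2 and 100 by 1 log2. On these the test of individual rats recovered 97% of changes of 0.5 log2 and 100% of changes of 1 log2 among 15866 probe sets, with 4.83% of its calls false. In pools of 2 it recovered 91% and 100%, with 5.45% false, and in pools of 3 78% and 97%, with 3.31% false. Correlation between probe sets was not simulated, so these rates need not hold for the real arrays.

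The lists not described with the results were cholesterol synthesis, LXR targets, brown adipocyte, endothelial, lymphocyte, macrophage, mast cell, skeletal muscle, nerve, skin, erythrocyte, cell cycle, oestrogen and progesterone response, immediate early, circadian clock, xenobiotic metabolism and interferon response. Their values stand among the other observations. Alternatives covered the normalization, a dim filter, the prior, array weights, the threshold, oestrous stage, a block by rat number, 1 probe set per gene, an exact rank-sum test and leaving out each array. Floors on linear values were planned in case the values were linear and do not apply.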

Results

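Expression was measured on 56 single-colour Affymetrix arrays hybridised with targets made from the mammary glands of female Wistar Furth rats, an inbred strain. Rats of 1 group received what the labels call RXR treatment and the others were controls. RXR is the usual abbreviation of the retinoid X receptor, a nuclear receptor that pairs with other receptors. The compound and the dose are not given in the sources used here. There were 12 treated and 12 control rats, each with an array of its own. Targets of the same rats were also combined into 6 treated and 6 control pools of 2, into 4 and 4 pools of 3, and into 1 treated and 1 control pool of 12, each hybridised 4 times. For 3 of the 4 arrays of each pool of 12 the source label reads individual, against title and description, which were followed. Treated rat 3 and control rat 3 had 2 further arrays each. By the labels, 6 treated and 9 control rats were in diestrus, and 6 treated and 3 control rats were in proestrus or estrus. The array medians lay between 7.40 and 7.48 log2. The number of arrays limits the precision, and the pools hold the same rats as the individual arrays, so the designs are not independent of each other.

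The leading comparison asked how treated and control glands differed. Lists of genes of fatty acid and triglyceride synthesis and of mitochondrial respiration were higher in treated rats by camera, and lists of epithelial and milk genes were lower. None of these calls held when the correlation between genes was estimated (smallest adjusted p = 0.112 with an estimated correlation). By permutation of the rats' list means, a test chosen after the data were seen, lipogenesis (adjusted p = 0.00018), respiratory chain and luminal lists (0.000135 each) passed. The milk (0.181) and basal lists (0.0706) did not. Of the other lists that camera called, adipocyte passed (0.00256), while PPAR targets (0.201) and fibroblast and matrix (0.181) did not. Pnpla3, a lipid droplet protein that insulin and carbohydrate feeding induce, had the largest rise, 2.91 ± 0.27 log2 (SE), from 7.42 ± 0.71 (SD, n = 12) in control rats to 10.3 ± 0.69 (SD, n = 12) in treated rats. Angptl8, a circulating regulator of lipoprotein lipase, rose by 2.53 ± 0.28. Elovl6, a fatty acid elongase, rose by 2.18 ± 0.29, and Me1, which supplies NADPH for lipid synthesis, by 1.92 ± 0.24. Slc2a4, the insulin-responsive glucose transporter, rose by 1.86 ± 0.21, while its other probe set gave 1.15. The other 7 of the 12 largest rises were Car5b, Mpc1, Acss2, Gys2, Pygl, Pdhb and Pdk1, from 2.67-fold for Pdk1 to 2.83-fold for Car5b. Mpc1 carries pyruvate into mitochondria, Pdhb and Pdk1 belong to the pyruvate dehydrogenase complex and its control, and Gys2 and Pygl make and break down glycogen. The probe sets of Pdk1 gave 0.84 and 1.42. In all 12 treated rats, each of these 12 genes lay above the control mean. The genes were chosen for the largest rises in these same rats, which favours such a count.

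The falls were smaller. Cyp2e1, a cytochrome P450, fell by 1.25 ± 0.21 log2 (SE), from 8.34 ± 0.76 (SD, n = 12) to 7.09 ± 0.13 (SD, n = 12). Pck1, the enzyme of glyceroneogenesis and gluconeogenesis, fell by 1.06 ± 0.30, and Cpt1a, which admits fatty acids to mitochondria, by 0.75 ± 0.19, with its other probe set at -0.34. The milk protein genes Wap and Lalba fell by 0.92 ± 0.24 and 0.89 ± 0.16. The remaining falls among the 12 were those of Scgb1d2-ps1, LOC102552398, Gp2, Rprm, Cd14, Reg3b and Plscr1, between -1.04 and -0.69. With limma and Benjamini-Hochberg adjustment, 2865 of 15866 probe sets passed an adjusted p of 0.05, 1343 higher and 1522 lower in treated rats. Of the 24 named genes the adjusted p ran from 1.47e-07 for Pnpla3 to 0.0279 for Gp2. Among rats in diestrus alone 1385 probe sets passed, 682 higher and 703 lower. In the 6 treated and 3 control rats not in diestrus 235 passed, 190 higher and 45 lower. Of the 2865 probe sets, 2857 had the same sign in both stages. They were called over the same rats that make up both stages, which favours the same sign.

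**Figure D1:**
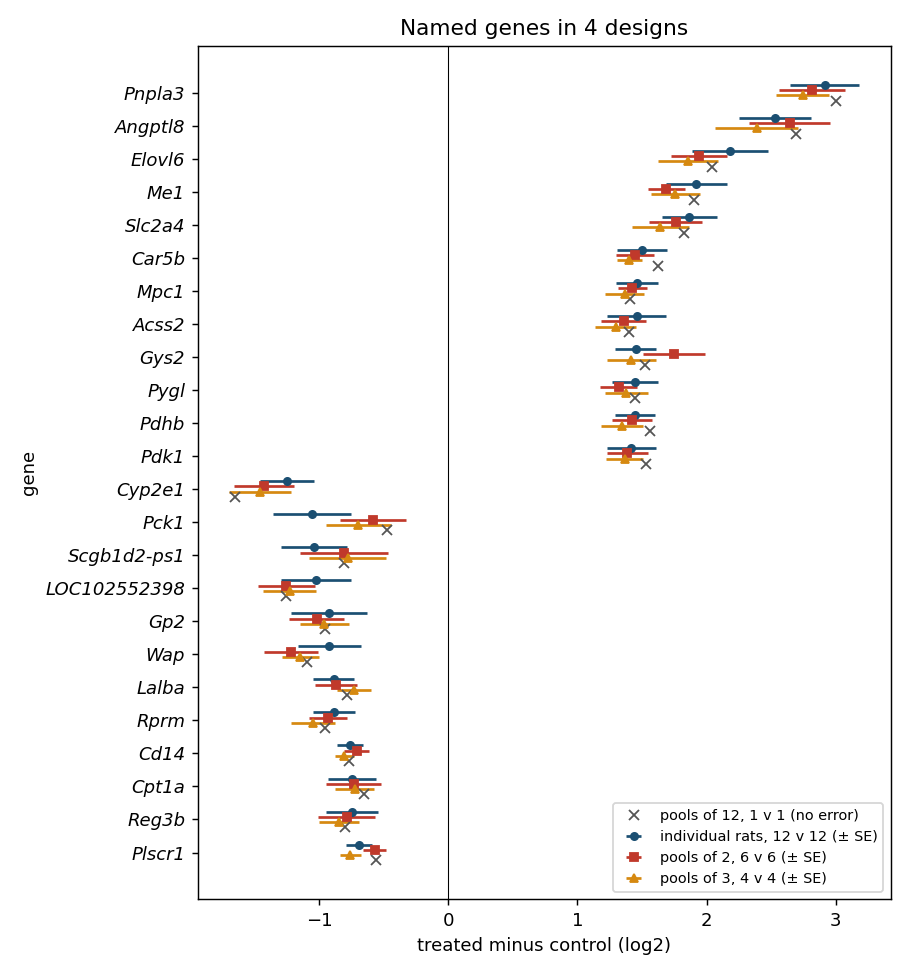
Treated minus control difference in log2 of the 12 genes with the largest rise and the 12 with the largest fall, in individual rats, pools of 2 and pools of 3 (points with SE) and in the pools of 12 (crosses, without error). All 24 genes lie on the same side of 0 in the 4 designs.

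Among the gene lists fixed before the data were examined, lipogenesis rose. Of its 23 measured genes 17 were higher and 1 lower, and the same numbers passed when adjusted over the list alone. Beside the genes above, Dgat2, which completes triglyceride synthesis, rose by 1.28 ± 0.14 (SE) and Thrsp, a lipogenic regulator, by 0.86 ± 0.10. The mean of the list was 10.7 ± 0.32 (SD, n = 12) in treated and 9.89 ± 0.31 (SD, n = 12) in control rats. Camera gave an adjusted p of 6.73e-13, and adjusted p = 0.179 with an estimated correlation. Of 22 respiratory chain genes, 21 were higher and 0 lower, 22 and 0 adjusted over the list alone. Ndufs1 of complex I rose by 0.81 ± 0.10, Uqcrc1 of complex III by 0.50 ± 0.06, Sdhd of complex II by 0.50 ± 0.06 and Atp5f1b of ATP synthase by 0.36 ± 0.03. The list had a camera adjusted p of 2.32e-22, and adjusted p = 0.112 with an estimated correlation.

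Adipocyte genes went both ways, with 10 of 17 higher and 2 lower over all probe sets and adjusted over the list alone. Lep, the hormone leptin, rose by 1.01 ± 0.11 (SE), Aqp7, a glycerol channel, by 1.10 ± 0.14 and Gpd1 by 1.17 ± 0.15. Cfd, the secreted adipocyte protein adipsin, fell by 0.69 ± 0.09. The camera adjusted p was 6.33e-05, and adjusted p = 0.714 with an estimated correlation. Of 32 genes of PPAR targets and fatty acid oxidation, 13 were higher and 4 lower, 15 and 8 adjusted over the list alone. Etfdh rose by 0.70 ± 0.08, Hadhb by 0.67 ± 0.08 and Cpt2 by 0.50 ± 0.07, all of them in mitochondrial fatty acid oxidation, and Ucp2 fell by 0.59 ± 0.10. That list passed with a camera adjusted p of 0.00305, and adjusted p = 0.714 with an estimated correlation.

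In the luminal list 12 of 20 genes were lower and 0 higher, 13 and 0 adjusted over the list alone, with a camera adjusted p of 2.05e-05, and adjusted p = 0.112 with an estimated correlation. Epcam fell by 0.43 ± 0.05 (SE), Cdh1, the adhesion protein E-cadherin, by 0.39 ± 0.07, Cldn7 by 0.47 ± 0.10 and the keratin Krt19 by 0.47 ± 0.10. In the milk and secretory list 7 of 14 genes were lower and 0 higher, 8 and 0 adjusted over the list alone, with a camera adjusted p of 0.00305, and adjusted p = 0.617 with an estimated correlation. Beside Wap and Lalba, Mfge8 fell by 0.50 ± 0.09 and Muc1 by 0.50 ± 0.10. In the basal list 5 of 12 genes were lower and 1 higher, 7 and 1 adjusted over the list alone, with a camera adjusted p of 0.0274, and adjusted p = 0.763 with an estimated correlation. Trim29 fell by 0.34 ± 0.07 and the contractile genes Mylk and Acta2 by 0.35 ± 0.08 and 0.36 ± 0.11, while Oxtr, the oxytocin receptor, rose by 0.90 ± 0.14. In the fibroblast and matrix list 5 of 22 genes were higher and 1 lower, 7 and 1 adjusted over the list alone, with a camera adjusted p of 0.00693, and adjusted p = 0.842 with an estimated correlation. Lox, which cross-links collagen, rose by 0.63 ± 0.16 and Fmod fell by 0.53 ± 0.12.

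**Figure D2:**
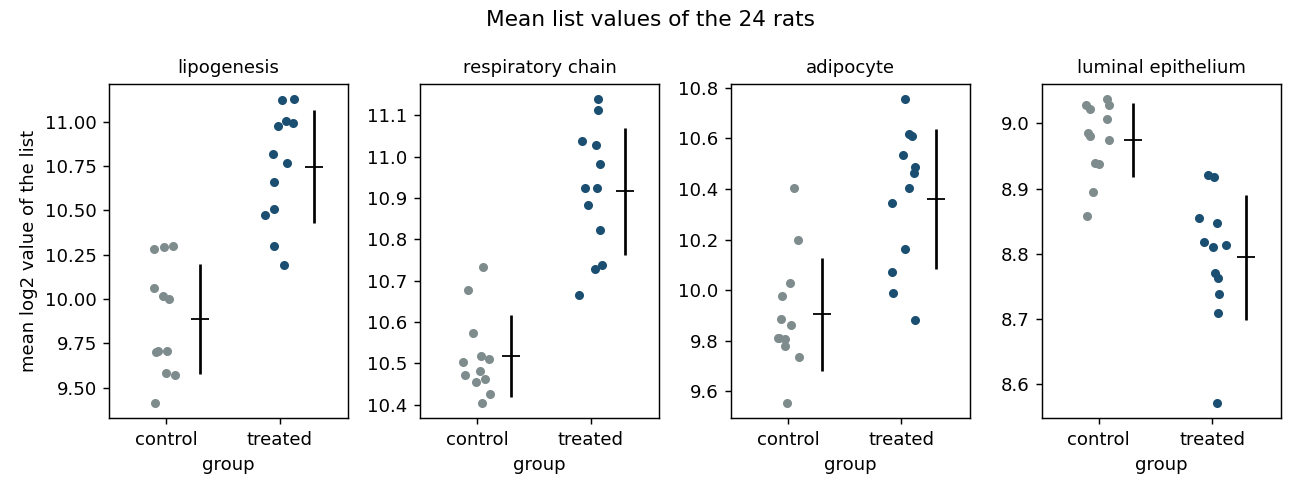
Mean log2 value of 4 gene lists in each of the 24 rats (points), with the group mean and SD beside them. The lipogenesis mean was 10.7 in treated and 9.89 in control rats, and the luminal epithelium mean was 8.79 in treated and 8.97 in control rats.

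The receptor genes themselves did not pass, with Rxra at 0.10 ± 0.05 (SE), Rxrb at -0.07 ± 0.04 and Rxrg at 0.09 ± 0.05. Among retinoid genes Rbp4, the retinol carrier, rose by 1.12 ± 0.16, Rarres2 rose by 0.51 ± 0.09 and Rdh10, a retinol dehydrogenase, fell by 0.57 ± 0.09. These were the 2 higher and 1 lower of 20 retinoid genes, also adjusted over the list alone, and the list had a camera adjusted p of 0.669. Its mean was 8.10 ± 0.05 (SD, n = 12) in treated and 8.04 ± 0.04 (SD, n = 12) in control rats (permutation test chosen after the data were seen, adjusted p = 0.0223). The median change of its genes was 0.03 and 17 of 20 did not pass. Rbp4 weighs heavily on so small a difference in means, so it does not show a rise of the list as a whole. Among the partners of the receptor, Pparg, a regulator of fat cell differentiation, rose by 0.76 ± 0.14, and the other 15 genes measured did not pass, also adjusted over the list alone (camera adjusted p = 0.737; median -0.00, mean 0.04).

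The pools asked whether combined targets gave the treatment difference of the single rats. In pools of 2, 1400 probe sets passed, 817 higher and 583 lower, and in pools of 3, 990 passed, 518 higher and 472 lower. With each array centred on its median, the pools of 3 gave 592 higher and 300 lower. The 24 named genes had the direction of the individual rats in both pool sizes, and 22 passed in each. The exceptions in both were Pck1, at -0.58 (adjusted p = 0.200) in pools of 2 and -0.70 (adjusted p = 0.138) in pools of 3, and Scgb1d2-ps1, at -0.81 (adjusted p = 0.182) and -0.78 (adjusted p = 0.168), all by limma. Pnpla3 rose by 2.82 and 2.75, and Cyp2e1 fell by 1.43 and 1.46. Without treated pool of 3 replicate 2 the pools of 3 gave 503 calls, without control pool of 3 replicate 3 they gave 650 and without control pool of 3 replicate 4 they gave 644. Between the pools of 12, which have no biological replicate and no test, Pnpla3 differed by 3.01 and Cyp2e1 by -1.66, and all 24 genes had the direction of the individual rats.

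Of the calls in individual rats, 1276 were shared in direction with pools of 2 and 884 with pools of 3. Independent lists of these sizes would share 125.1 and 89.1. The differences correlated at r = 0.943 and 0.917 across all probe sets, which are not independent replicates. Simulated rats without a treatment effect, pooled in the same way, gave r = 0.581 and 0.518, since the designs share their rats. The covariance was 0.0306 for pools of 2 against 0.0032 simulated, and 0.0302 for pools of 3 against 0.00319 simulated.

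The spread between arrays of a group was compared by kind. Relative to individual rats, the geometric mean ratio of variances was 0.886 in pools of 2, 0.906 in pools of 3 and 0.622 between repeat arrays, which are those of the same rat or of the same pool of 12. In pools of 3 it was 0.801 among treated and 1.02 among control arrays. The ratios of mean variances, which weigh the most variable genes more, were 0.761, 0.682 and 0.415. If pooling averaged the rats and left the array error as it was, the mean variances would give 0.708 and 0.61. The repeat arrays, from which the array error was taken, include control pool of 12 replicate 3. Its deviations correlated with those of the first array of its pool at only r = 0.0801. With the main axis of difference between repeat arrays removed, a step chosen after the data were seen, the mean variances gave 0.748, 0.64 and 0.196, and averaging would give 0.598 and 0.464. That axis was fitted on the repeat arrays themselves, which lowers their variance and these last values by construction, so the removal does not test averaging. Between rats, Glycam1 varied most, with an SD of 2.56 log2 against 0.0637 between repeat arrays, followed by the milk protein gene Csn2, with 1.70 against 0.0901. These 2 genes were chosen after their values were seen.

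Each pool was also set against log2 of the mean linear value of its member rats. The median absolute difference was 0.08 log2 in pools of 2 and 0.0869 in pools of 3. Pools that hold treated or control rat 3 followed their members least. Each of them also holds rat 2 of the same group, so the part of either rat cannot be told apart. Across probe sets, which are not independent replicates, deviations of pool and members correlated there at r = 0.105 and 0.0631 in pools of 2. In pools of 3 it was 0.178 and 0.0622, against medians over all pools of 0.597 and 0.514. The technical scores of these pools lay 14.5 to 22.2 above those of their members. By limma, 0 probe sets passed in pools of 2 and 1 in pools of 3, Gadd45gip1, at 0.25 ± 0.04 (SE) with an adjusted p of 0.0267. These counts do not show that pools equal their members, since 3961 and 3722 probe sets had an unadjusted p under 0.05. Without control pool of 2 replicate 3 the count was 826 and without treated pool of 3 replicate 1 it was 591. The smallest p in pools of 2 belonged to Tbpl1 at 0.23, Tcam1 at -0.23, Fgf2 at -0.17 and Zfp292 at -0.19, each with an adjusted p of 0.0515.

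Oestrous stage gave no call with treatment as a covariate. By limma 0 of 15866 probe sets passed, and 581 had an unadjusted p under 0.05. The smallest p values belonged to Obp3, at 1.04 ± 0.19 log2 (SE) higher outside diestrus, and Agt, the precursor of angiotensin, at 1.07 ± 0.20, both with an adjusted p of 0.188. Acss1, Hacd3, Il17re and Elf2 followed, at -0.32, 0.19, -0.15 and -0.18. Without control individual replicate 3 the count was 1. Of 27 gene lists 5 passed camera, 2 higher and 3 lower outside diestrus, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.872. The cell cycle list had the smallest, adjusted p = 0.000134, and was lower outside diestrus, with 0 of 24 genes passing alone. Respiratory chain (adjusted p = 0.00162) and skin genes (0.0195) were higher as lists, and circadian clock (0.0238) and fibroblast and matrix genes (0.0283) lower, each with 0 genes passing over all probe sets and 0 adjusted over the list alone by limma. The skin list rested on treated rats 3 and 10, both outside diestrus, whose means were 8.68 and 9.89 against 7.54 or less in the other rats outside diestrus; without both its direction turned (adjusted p = 0.499). Each of the other 4 lists also missed the threshold without some single rat, with an adjusted p of 0.108 for the cell cycle without treated rat 9, 0.114 for the respiratory chain without control rat 8, 0.105 for the circadian clock without treated rat 4 and 0.506 for fibroblast and matrix without treated rat 8. For the treatment by stage interaction 0 probe sets passed by limma and 322 had an unadjusted p under 0.05. The smallest p values were those of Smtn at 0.38, Med22 at 0.33, Trim11 at 0.21 and Arhgef17 at 0.28, each with an adjusted p of 1.

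**Figure D3:**
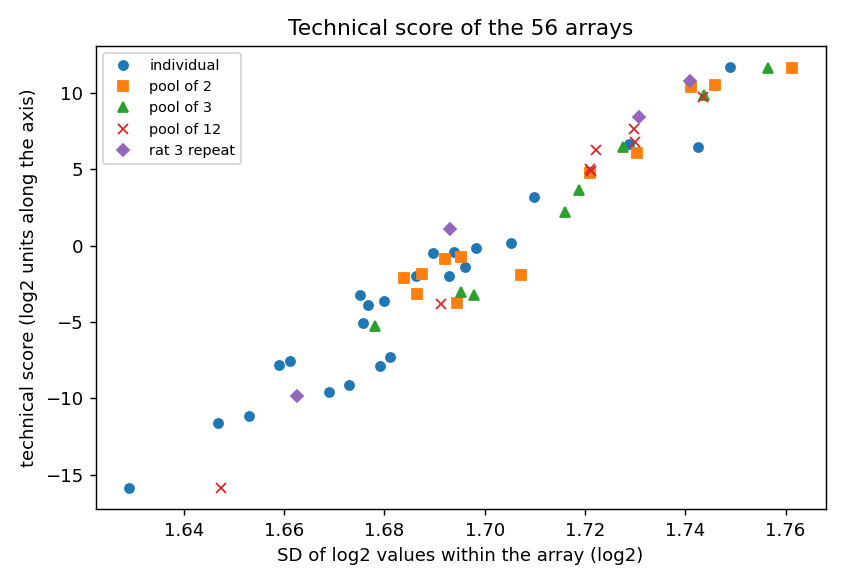
Technical score of each of the 56 arrays (log2 units along the main axis of difference between repeat arrays) against the SD of its log2 values. The scores of individual rats ran from -15.9 to 11.7 and those of the pools of 12 from -15.9 to 9.69.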

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

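The tests of the adipocyte share, the epithelial share, the technical score and log averaging were chosen after the results were seen, as were the splits by stage and for the interaction. The splits by treatment and the tests by oestrous stage and of fasting genes were chosen before the values they measure were seen.

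Lipogenesis genes were 0.86 log2 higher in treated rats as a list mean. Each rat's lipogenesis mean minus its adipocyte mean was 0.40 higher in treated rats (permutation test, p = 0.00012). This would argue against a larger share of adipocytes alone if that share raised both lists by the same log2 amount. That was not tested, and adipocyte genes went both ways, so a larger share is not excluded. Unequal stages are argued against by a difference of 0.81 among the rats in diestrus (permutation test, p = 0.00057), and the technical score by a difference of 0.88 ± 0.12 (SE) with that score as a covariate. A hypothesis of feeding state predicted a fall of 14 measured genes that fasting induces. Their mean differed by -0.0176 (permutation test, p = 0.826), with 3 lower (Irs2, Txnip and Foxo3) and 0 higher, so the prediction was not met. Feeding state stays open, beside a larger adipocyte share and an effect of the treatment.

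The luminal, basal and milk lists were lower in treated rats by camera. The technical score is argued against by a luminal difference of -0.18 ± 0.03 (SE) with it as a covariate. A smaller epithelial share could account for this and stays open: over all rats the difference between the luminal and basal changes was 0.0202 (permutation test, p = 0.772), though Oxtr of the basal list rose. By stage, the luminal mean differed by -0.19 in diestrus and -0.16 outside it and the basal mean by -0.29 and -0.06 (camera adjusted p = 0.398 outside diestrus), with a treatment by stage difference that did not pass for the basal list (permutation test, adjusted p = 0.762). Lower expression per epithelial cell was not tested.

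Pools of 3 lay above the mean of their members' log2 values in 460 of 578 called probe sets, by a median of 0.16 log2, and below it in 118. Since these were selected for their excess, probe sets were instead chosen as higher in 7 pools and measured in the pool held out, where the median excess averaged 0.12 ± 0.03 (SE, n = 8 pools). Part of it may come from averaging on the log scale, since the held-out excess followed the gap between both averages in the other pools' members with a slope of 1.01 ± 0.21 (SE). Against log2 of the members' mean it was 0.0919 ± 0.0235 (SE), and with the part that follows the technical score removed 0.0997 ± 0.025 (SE), so neither alone accounts for the whole. No biological explanation was tested.

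Other splits of the samples gave fewer treatment calls than the real ones. In individual rats 1 of 100 splits, the real one, gave 2865 calls, and the highest other gave 1. In pools of 2 it was 1 of 100, with 1400 calls against 38, and in pools of 3 it was 1 of 35, with 990 against 1. For these 3 counts the real split gave the most calls, which argues against chance, but 100, 100 and 35 splits are too few to exclude it. Any other split puts treated and control samples into the same group. A treatment difference then widens the spread within that group and can lower the calls, so the low counts do not show what no effect would give. For stage and for the interaction the real count was 0, which each of the 100 splits reaches whatever its calls, so the splits decide nothing there. The highest others, 840 and 1228, point to a structure of the samples, whose nature was not examined.

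The 3 probe sets for Gapdh among the array's controls, which no comparison used, were higher in treated rats by 0.50, 0.41 and 0.41 log2, with adjusted p of 6.02e-05, 0.000306 and 0.00202 over the 57 control probe sets by limma.

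Of 180 sets of pool arrays and measures, 12 held an array far from the others of its group, where chance gives about 9. Control pool of 12 replicate 3 had a technical score of -15.9 against 5.02 to 7.64. The technical axis was fitted on arrays that include this one, so that score is partly built in. The array's lipogenesis mean was 9.97 against 10.02 in the other 3 arrays. Its xenobiotic mean was 7.34 against 7.24 to 7.26 and its respiratory chain mean 10.5 against 10.61 to 10.63. Treated pool of 12 replicate 1 had a retinoid mean of 8.13 against at most 8.06 and a lymphocyte mean of 6.22 against 6.17 to 6.18. The interferon mean was 8.17 in treated pool of 3 replicate 3 against 7.98 to 7.99. The luminal mean was 8.69 in treated pool of 2 replicate 4 against 8.84 to 8.88. The skin mean was 7.88 in control pool of 3 replicate 3 against 7.58 to 7.60, and 7.94 in control pool of 2 replicate 5 against 7.44 to 7.62. The xenobiotic mean was 7.20 in control pool of 3 replicate 4 against 7.27 to 7.28, and the lymphocyte mean was 6.09 in control pool of 2 replicate 4 against 6.19 to 6.25.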

How the results depend on the processing

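The technical score as a covariate, the mean variances, the removal of the technical axis, the permutation of list means, the omission of treated rats 3 and 10 or of each rat for lists under stage the estimated correlation in pools and the 20 rats unblocked for genes and lists were chosen after seeing the data. In individual rats the count of 2865 became 1733 at an adjusted p of 0.01, 1385 in diestrus and 235 outside it, where fewer rats were tested, and lay between 2520 and 3133 with any 1 rat left out. The exact rank-sum test gave 2647 and the omission of treated rat 10 gave 2774. The rat number as a block gave 2535 calls in 20 rats against 2589 in the same rats without it. No pairing by number was detected, which does not exclude one. Same-numbered rats' deviations correlated between -0.389 and 0.358, with 5 of 10 over 0.1, and 1 of 10 treated rats matched its own number best. In these 20 rats Gp2 (adjusted p = 0.0646, blocked 0.0855) and the lists of PPAR targets (0.0514, blocked 0.0822) and basal epithelium (0.134, blocked 0.147) missed the threshold without the block too, and cholesterol synthesis passed (0.00153, blocked 0.000154). Pools of 2 gave 591 at 0.01 and 956 to 1559 with any 1 pool left out. Pools of 3 gave 378 at 0.01, 1561 with array weights, 1517 with the technical score and 503 to 1020 with any 1 pool left out; the cause was not tested.

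Pools of 2 against their members gave 140 calls with the mean of log2 values, 49 after quantile normalization, 2 with the technical score and 0 to 826 with any 1 pool left out. Pools of 3 gave 578, 51, 12 and 0 to 591, and 0 in treated and 0 in control pools alone. The cause was not tested beyond log averaging and the technical score. Pools whose omission gave over 1 call were control pool of 2 replicates 3 and 6 and treated pool of 2 replicates 4 and 5, with 826, 414, 20 and 110, and treated pool of 3 replicate 1 and control pool of 3 replicates 1 and 2, with 591, 11 and 496; without treated pool of 3 replicates 2, 3 or 4 or control replicate 4 the count was 0. Among the 100 smallest p of each design, 48, 40 and 54 were shared. The spread between repeat arrays was 0.361 with the technical axis removed, and the pools' ratios kept within 1.5 times. The 12 named fallers differed by -0.96 between the first arrays of the pools of 12 against -0.90 over all, and the 12 risers kept between 1.78 and 1.86 with any 1 array left out, the fallers between -0.92 and -0.89. Stage gave 0 to 1 calls with any 1 rat left out and the interaction 0.

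Of the 27 lists, 8 passed under treatment, 0 with an estimated correlation, also in pools of 2 and of 3, and 8 to 9 with any 1 rat left out. With permuted list means 6 passed: lipogenesis, respiratory chain, adipocyte and luminal, and also retinoid and mast cell, which camera did not call. Under stage 5 of the 27 passed, 0 with an estimated correlation, 8 in treated rats alone and 1 to 10 with any 1 rat left out: 10 without treated rat 7, 8 without treated rat 14 or control rat 10, and 1 without treated rat 9. Without treated rats 3 and 10 the skin list turned (adjusted p = 0.499). In control rats alone the stage direction turned for fibroblast and matrix (adjusted p = 0.869), skin (0.221) and erythrocyte (0.0138). None of the 12 named risers and 12 named fallers changed sign under the settings run for them. Of these 24, 5 did not pass in diestrus alone and 11 outside diestrus alone, with fewer rats.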

Other observations

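The tests of list means by permutation and the random draws of rats were chosen after the data were seen. Of 10 mast cell genes 2 were lower and 0 higher in treated rats, over all probe sets and adjusted over the list alone. Tpsab1, a tryptase, fell by 0.48 ± 0.08 log2 (SE) and Kit, the stem cell factor receptor, by 0.54 ± 0.14. The list had a camera adjusted p of 0.352 and a permutation adjusted p of 0.00578. Its median change was -0.04 against a mean of -0.14, and 8 of 10 genes did not pass. The mean thus leaned on the 2 lower genes and does not show a fall of the list as a whole. Of 14 macrophage genes 4 were higher and 1 lower: Csf1r, the receptor of macrophage growth factor, rose by 0.30 ± 0.08 and Lyz2 by 0.25 ± 0.07, while Cd14, a receptor for bacterial lipopolysaccharide, fell by 0.76 ± 0.10, and the list did not pass in individual rats (camera adjusted p = 0.145). It passed in rats in diestrus (0.00401) and in pools of 2 (0.0339, and adjusted p = 0.573 with an estimated correlation) but not in pools of 3 (0.261). Outside diestrus the difference in its mean was -0.05 log2 (0.845) against 0.12 in diestrus, and the treatment by stage difference did not pass (permutation test, adjusted p = 0.762). In the nerve list S100b, which adipocytes also express, rose by 1.15 ± 0.12, while Cnp and Sox10 of Schwann cells fell by 0.53 ± 0.10 and 0.25 ± 0.07 (camera adjusted p = 0.814).

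Of 17 cholesterol synthesis genes 2 were higher, Nsdhl by 0.65 ± 0.14 (SE) and Sc5d by 0.45 ± 0.11, with a camera adjusted p of 0.0545 in individual rats, 0.00446 in pools of 2 and 0.00186 in pools of 3. Individual rats gave adjusted p = 0.842 with an estimated correlation and pools of 2 gave 0.749, and pools of 3 did not pass with one either. Of 13 LXR targets 2 were higher and 3 lower: the desaturase Scd rose by 0.51 ± 0.09 and the cholesterol transporter Abcg1 fell by 0.38 ± 0.10 (camera adjusted p = 0.428). Of 15 xenobiotic genes 3 were higher and 1, Cyp2e1, lower (0.38). Of 15 genes of oestrogen and progesterone response 1 was higher, the protease Ctsd by 0.74 ± 0.10, and 2 lower (0.647). Of the xenobiotic genes Gstm1 rose by 0.44, and the list had a median of 0.03 and a mean of -0.02. Adjusted over the list alone, the counts of the lists named here were the same, except for 5 higher macrophage genes. The camera adjusted p was 0.764 for immediate early genes, where Dusp1 rose by 0.64 ± 0.18, 0.764 for the circadian clock, 0.16 for skeletal muscle and 0.729 for endothelium, each with 1 gene passing, Bhlhe41 at -0.36, Myl1 at 0.21 and Vwf at -0.28 in the latter 3. It was 0.737 for brown adipocytes (median 0.02, mean -0.02), 0.433 for lymphocytes, 0.603 for skin, 0.759 for erythrocytes, 0.884 for the cell cycle and 0.366 for interferon response, each with 0 genes passing. By stage, the erythrocyte mean differed by 0.29 in diestrus (camera adjusted p = 0.296) and -0.29 outside it (0.0101). Its treatment by stage difference did not pass (permutation test, adjusted p = 0.762).

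Rats differed in markers of tissues other than the gland. The skin list averaged 9.89 log2 in treated rat 10 and 8.68 in treated rat 3, while the other 22 rats lay at or below 7.93.

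Random draws of 6 treated and 6 control rats gave a median of 1145 calls by limma, from 99 to 3306, and 36 of 100 draws reached the 1400 of the pools of 2. Draws of 4 and 4 rats gave a median of 214, from 0 to 1896, and 13 of 100 reached the 990 of the pools of 3.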
